A study of Triticum aestivum with 6 samples.

How the data were processed

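Total RNA from flag leaves at anthesis was hybridised as biotin-labelled cRNA, 1 array per sample, per the labels' protocols. The deposited values are on a log2 scale, 1 per probe set and array; the submitters' processing notes name RMA and GCRMA, which summarise the probes of a set after background correction and quantile normalization, without version, role or order. The shared lowest value of 2.18 on all 6 arrays fits a background-corrected scale, and values at this floor carry no order; a difference against the floor is understated.

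Groups were taken from the labels: 3 Bobwhite control samples, numbered 1 to 3 here in the order of their records, and the 3 lines a20, b2 and b36. The table held 61290 probe sets. The 111 Affymetrix control probe sets and 64 reporter probe sets were left out of the test, which left 61115, and those above the table median of 2.50 on at least 3 of 6 arrays were tested, 30443 in all. Values were used as deposited, with no further normalization. The test was limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided), lines minus controls, with Benjamini-Hochberg adjustment and a threshold of 0.05. With 3 arrays against 3, an exact permutation test of a single probe set cannot go below 0.1, so none was used. A separate fit added the reporter probe sets, and another the wheat control probe sets. The median residual SD was 0.147 and the prior degrees of freedom 0.884.

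Gene names came from the platform annotation, which can be old, updated through the gene identifiers of the RefSeq table for assembly IWGSC CS RefSeq v2.1; no coordinates were used. Of the 61115 probe sets, 1273 had 1 locus, 0 had several and 59842 had none here, and 770 of 771 loci matched. Only 200 probe sets, 118 of them tested, carried a name beyond a bare locus number, and the tables hold no gene descriptions, so gene lists were matched on symbols and synonyms alone.

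The design, the alternatives, the 20 gene lists and the rule for named genes were fixed before the data were examined. The rule took any MYB13 probe set, the fructan synthesis and hydrolysis lists, the genes with the largest changes past the threshold (or, as none passed, the 5 with the lowest p in each direction), and up to 4 members per list with the lowest p; it gave 32 probe sets. The unnamed loci at least 2-fold apart and the unnamed probe sets were added after the values were seen, and the latter are described by their values without an ID. Lists with at least 3 tested probe sets were tested with camera (preset correlation 0.01, and an estimated correlation) and fry, adjusted over 6 lists. No further test was made for single lines, each of which has 1 array.

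Alternatives covered the filter, median centring, quantile normalization, variance model, array weights, thresholds, a pooled-variance test, probe sets open to cross-hybridisation, 1 value per gene, and leaving out each array. The steps were tested on 10 sets of simulated data with 200 of 30443 probe sets changed: limma recovered 55.1% of the 2-fold, 81.9% of the 4-fold and 95.5% of the 16-fold changes, with 10.6 false calls on average. The simulated noise was independent between probe sets, without the differences between whole arrays seen in the real data. These shares therefore do not measure how many real changes of such sizes the test would miss. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.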

Results

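Transcript levels were measured in flag leaves of bread wheat, the uppermost leaves of the shoot, collected at anthesis, the time of flowering. Each of the 6 samples was hybridised to 1 Affymetrix wheat array. Of these, 3 samples came from control plants of Bobwhite, a spring wheat cultivar widely used for transformation, and 3 from the transgenic lines a20, b2 and b36, 1 array per line. The lines overexpress TaMYB13, a MYB transcription factor studied in wheat as a regulator of the synthesis of fructans, the fructose polymers that temperate cereals store in their vacuoles. Plants had grown in 16 h days at 20 °C and 90% humidity and 8 h nights at 16 °C and 60% humidity. Values are log2 signals as deposited, with a common floor of 2.18 that held 35.8 to 36.4% of the probe sets on each array. The number of arrays limits the precision. The labels do not say whether the control samples came from separate plants, so p-values measure only the spread between these samples, which for the lines includes differences between lines.

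The comparison of TaMYB13-overexpressing lines with controls asks which transcripts differ between the flag leaves of these lines and of Bobwhite. The labels do not say whether the controls were transformed. An effect of TaMYB13 therefore cannot be told apart from an effect of transformation. Among named genes of fructan metabolism, 6-FEH (LOC780575), a fructan exohydrolase that removes fructose units from fructans, had higher values in all 3 lines than in all 3 controls. Its first probe set read 9.30 ± 0.66 in controls and 10.74 ± 0.79 in the lines (SD, n = 3 each), a log2 difference of 1.44 with an SE of 0.54. The second 6-FEH probe set read 10.26 ± 0.37 and 11.09 ± 0.52, a log2 difference of 0.83 with an SE of 0.34. This difference was 0.54 without line b36 and 1.03 without line b2. The related exohydrolase 1-FEH (LOC543441) was at 12.30 ± 0.12 in controls and 12.37 ± 0.32 in the lines, a difference of 0.07 that lay within the spread of the lines. Neither gene passed the test, with limma adjusted p values of 0.848 for both 6-FEH probe sets and 0.964 for 1-FEH.

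Several loci without a gene name in the annotation used here differed by more, and they are given because their values stood out after the data were seen. LOC542773 read 12.70 ± 1.63 in controls and 15.14 ± 0.41 in the lines, a log2 difference of 2.44 with an SE of 0.88, or 5.44-fold. LOC542774 read 10.79 ± 1.45 and 13.22 ± 0.38, a log2 difference of 2.43 with an SE of 0.78, and LOC780687 8.56 ± 1.64 and 11.11 ± 0.48, a difference of 2.55 with an SE of 0.89. Second probe sets of LOC542773 and LOC780687 gave log2 differences of 2.08 and 3.33. LOC778386 read 5.68 ± 0.75 in controls and 7.43 ± 1.01 in the lines, with line b2 at 6.26 close to the highest control at 6.19. For all of these probe sets the 3 lines lay above the 3 controls, and the limma adjusted p was 0.848. Control 3 held the lowest value of each: 10.93 for LOC542773, 9.17 for LOC542774, 6.72 for LOC780687 and 4.82 for LOC778386. Without control 3 the differences were 1.56, 1.62, 1.62 and 1.31, and that of the first 6-FEH probe set was 1.06. Without line b36, this 6-FEH difference was 0.997. Without control 2 those of LOC542773, LOC542774 and LOC780687 were 3.17, 3.02 and 3.18, and without line b2 that of LOC778386 was 2.33. A sign of RNA quality lay in the same direction. The 3' minus 5' difference of the sucrose synthase control probe sets was 6.06 ± 0.14 in controls and 6.51 ± 0.32 in the lines. That of glucose-6-phosphate dehydrogenase was 4.40 ± 0.06 and 4.63 ± 0.22, with every line above every control on both genes. Ubiquitin did not show this: its 3' and 5' control sets differed by 0.05 and 0.03 between the groups, with overlapping values.

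**Figure D1:**
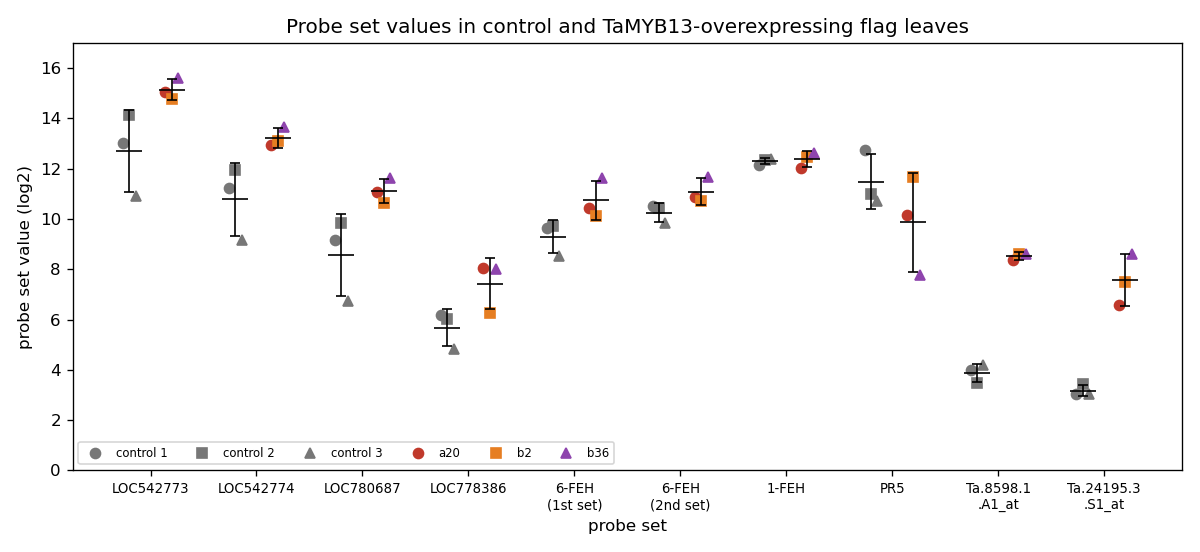
Log2 values of 10 probe sets on each array, with grey symbols for the 3 control samples, coloured symbols for lines a20, b2 and b36, and black bars for the group mean with its SD (n = 3). LOC542773, LOC542774, LOC780687, LOC778386 and 6-FEH lie higher in the lines with control 3 lowest, 1-FEH overlaps, and PR5 spreads widely in both groups.

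The difference with the smallest p belonged to a probe set without a gene name here, chosen after its values were seen. It read 3.88 ± 0.37 in controls and 8.52 ± 0.15 in the lines (SD, n = 3 each), a log2 difference of 4.64 with an SE of 0.21, and each line lay between 8.35 and 8.61. Its limma adjusted p was 0.126, and it passed with an adjusted p of 0.0175 when each array was centred on its median and of 0.0428 after quantile normalization, within a range up to 0.784 over the alternatives. A second unnamed probe set read 3.17 ± 0.23 in controls and 7.57 ± 1.03 in the lines, a difference of 4.40. Other probe sets with the same ID number differed by 4.03, with a limma adjusted p of 0.605, and by 1.32, both with separated groups. The largest negative differences among unnamed probe sets with an unadjusted p under 0.001 were -1.55 and -1.38. The adjusted p of these last 3 probe sets was 0.848. Larger falls had an unadjusted p between 0.001 and 0.05, the range that also held LOC542773, LOC542774 and LOC780687. Among unnamed probe sets with separated groups in this range, some falls were more than 4-fold, and they reached more than 16-fold. Control 3 was the highest array for the fall of more than 16-fold. These falls also had a limma adjusted p of 0.848.

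Besides 6-FEH, the named genes with the lowest p values had smaller differences. PCS1 (LOC542834), a phytochelatin synthase that makes metal-binding peptides, read 8.45 ± 0.03 in controls and 8.04 ± 0.13 in the lines, a log2 difference of -0.41 with an SE of 0.07. The histone gene wcH2B-8 (LOC543184) differed by -0.34, raftin1b (LOC543009), named for an anther protein, by -0.57, and the xylanase inhibitor gene xip (LOC542997), whose groups overlapped, by -0.53. On the higher side, both probe sets of TEF1 (LOC543386), a translation elongation factor, differed by 0.14 and 0.16, and eIF-2-beta (LOC543269), a subunit of a translation initiation factor, by 0.17. All of these had a limma adjusted p of 0.848. The histone gene H2A-9 (LOC732714) had differences of either sign, -0.32 for 1 probe set and 0.81 for another, with control means of 5.22 and 4.82. The set at 0.81 is of a type open to cross-hybridisation. So are those given for wcH2B-8, raftin1b and TEF1, and the second 6-FEH set. The negative difference was -0.20 without line a20, and the positive one was 1.24 without line b2 and 0.56 without line b36.

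Across the array, limma called 0 of 30443 tested probe sets at an adjusted p under 0.05, with 1483 (4.87%) at an unadjusted p under 0.05, of which 727 were higher and 756 lower in the lines. The pooled-variance test, limma with a variance trend and with array weights, and treat also called 0 each. The groups were separated, with all lines on one side of all controls, for 2455 probe sets (8.06%), where chance gives 10%. Of the 333 probe sets whose means differed at least 2-fold, 102 were also separated with an unadjusted p under 0.05, 50 higher and 52 lower. Only 5 of those 102 had a locus in the annotation, and all 5 were higher: the 4 unnamed loci above and 6-FEH. Control 3 had the lowest control value in 41 of the 50 higher probe sets and the highest in 32 of the 52 lower ones. The count of 102 was 61 without control 3, 65 without line b36, 187 without control 2 and 193 without line b2, and the count of 1483 was 2457 without line b2. With each array centred on its median, 63.0% of the probe sets at an unadjusted p under 0.05 were higher in the lines, against 49.0% as deposited.

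**Figure D2:**
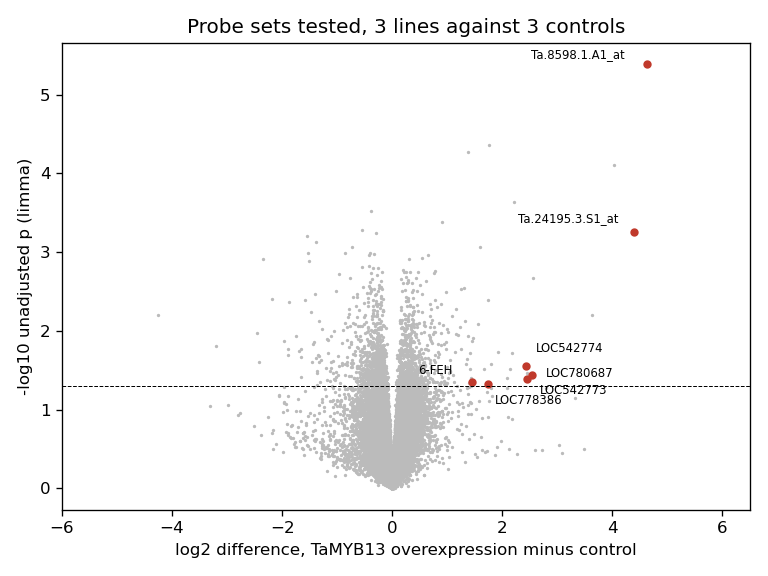
Each point is a tested probe set, with the log2 difference (lines minus controls) on the x axis and the negative log10 of the unadjusted limma p on the y axis; the dashed line marks an unadjusted p of 0.05. The unnamed probe set with the smallest p lies farthest up at a log2 difference of 4.64, and LOC542773, LOC542774 and LOC780687 lie at 2.44, 2.43 and 2.55 just above the line.

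No probe set carried a MYB gene or a fructosyltransferase name in the annotation, so the TaMYB13 transcript and the genes of fructan synthesis could not be picked out by name. The annotation gives no function for LOC542773, LOC542774, LOC780687 and LOC778386, and genes of fructan synthesis may be among them. Of 20 gene lists, 9 had a tested probe set and 6 had the 3 needed for a set test. No list member passed over all tested probe sets or adjusted over the list alone. The fructan exohydrolases (6-FEH and 1-FEH, 3 probe sets, all with positive differences) had a median log2 difference of 0.83 and a camera adjusted p of 0.115, against an adjusted p of 0.744 with an estimated correlation and 0.690 by fry. This camera adjusted p was 0.0138 without line a20 and 0.0149 without the filter on dim probe sets, within a range up to 0.342 over the alternatives. With an estimated correlation these became adjusted p values of 0.592 and 0.607.

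The few photosynthesis genes with a name here, PsbO, PsbP, rbcl and PRK, differed by little. The photosystem genes PsbO (LOC543291), at 14.76 ± 0.10 in controls and 14.80 ± 0.04 in the lines, and PsbP (LOC543290), at 15.17 ± 0.07 and 15.18 ± 0.05 for its brighter probe set, encode proteins of the oxygen-evolving complex; the sign of the PsbP difference turned under quantile normalization. The carbon fixation list held 17 tested probe sets, 16 of them for rbcl (LOC100049018), the large subunit of Rubisco, and 1 for PRK (LOC543283), phosphoribulokinase. Its median log2 difference was 0.08, with 13 higher and 4 lower, and the camera adjusted p of 0.330 became 0.00486 without control 3, where the median was 0.11. With an estimated correlation the adjusted p was 0.744 with all arrays and 0.296 without control 3, and fry gave 0.690 and 0.364. The rbcl probe sets ranged from -0.34 to 0.34, and PRK was at 0.02. The 4 rbcl probe sets with the lowest p had control means from 4.27 to 8.91, well below those of PsbO and PsbP. The list test therefore mostly describes probe sets of 1 gene, and says little about carbon fixation as a whole.

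For starch, BMY1 (LOC543318), a beta-amylase, read 4.71 in line a20 and 4.72 in b36. Line b2 and control 2 both read 2.32 and controls 1 and 3 both 2.95, repeated low values around the table median of 2.50 that are not shown to be above background. AGP-S (LOC543299), the small subunit of ADP-glucose pyrophosphorylase, differed by 0.11. In the defence list, PR5 (LOC543292), a thaumatin-like pathogenesis-related protein, read 11.48 ± 1.08 in controls and 9.87 ± 1.97 in the lines, with b36 at 7.77 and b2 at 11.68. Its log2 difference of -1.61 was -0.57 without b36 and -2.52 without b2. The peroxidase PER1 (LOC543108) differed by 0.03, with low values of 3.07 to 3.39 that are also not shown to be above background. COMT1 (LOC543449), a methyltransferase of lignin synthesis, differed by 0.04. The histone and cell division list held 6 tested probe sets, all of H2A-9 and H2A-3 (LOC732713), and did not include wcH2B-8. This list and the ribosome list (3 probe sets, for RPS29 and RPL9) had medians of -0.0048 and 0.02, each with a camera adjusted p of 0.550. Fry's test for change in either direction gave the histone list an adjusted p of 0.618, and 0.00118 without line a20 and 0.0270 without b2. The photosystem list had a camera adjusted p of 0.798.

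As a check for other tissues, the anther and pollen list held 4 tested probe sets of raftin1b and profilin (LOC543315), with a median of -0.05 and a camera adjusted p of 0.330. Fry's test for change in either direction gave an adjusted p of 0.618, and 0.00185 without line b36. Profilin, an actin-binding protein that is abundant in many tissues, was at 14.46 ± 0.06 in controls and 14.36 ± 0.12 in the lines. The second raftin1b probe set read 2.60 on all arrays. The lists for grain storage proteins, epidermis and wax, and vascular tissue had 0 tested probe sets.

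Compared singly with the control mean, 1 array per line gives no spread within a line. Line b36 had 961 probe sets at least 2-fold from the control mean and outside the control range (338 higher, 623 lower), a20 had 416 (192 and 224) and b2 had 324 (138 and 186). The controls, each set against the mean and range of only the other 2, had 381, 480 and 549, so these counts are not directly comparable. With 1 control left out, and so also against 2 controls, the counts were 382 to 565 for a20, 236 to 505 for b2 and 992 to 1078 for b36. For the first 6-FEH probe set, a20, b2 and b36 lay 1.16, 0.84 and 2.33 above the control mean, and for LOC542773 2.34, 2.09 and 2.90. Against all 3 controls, 39 probe sets were higher and 28 lower in all 3 lines together by this measure, and the 5 of these with a locus belonged to LOC542773, LOC542774 and LOC780687. Simulated data without a group difference, with lines and controls both redrawn with independent normal noise, gave on average 18.5 and at most 24 higher. They gave on average 20.5 and at most 29 lower, over 20 draws. The draws do not keep the way control 3 and line b36 stood apart, so they cannot show how much that adds. Independent lists of these lengths would share only 0.00966 higher and 0.0280 lower. The draws, where the lines also share their controls, already gave averages of 18.5 and 20.5 without a group difference. The excess over independent lists therefore does not by itself show a shared change. Line b2 had 505 such probe sets without control 1 and 502 without control 2.

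Arrays were compared with each other across the tested probe sets. Pearson correlations across probe sets, which are not independent replicates, were 0.9895 to 0.9931 among controls, 0.9875 to 0.9933 among lines and 0.9863 to 0.9946 between groups. The first principal component took 36.1% of the variance and placed b36 at 57.4 against -23.4 to 12.1 for the rest. The second took 29.1% and placed control 3 at 51.8. Without control 3 and b36, a setting chosen after seeing the data, limma again called 0, with 924 at an unadjusted p under 0.05 and 49 that were also separated and at least 2-fold apart.

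**Figure D3:**
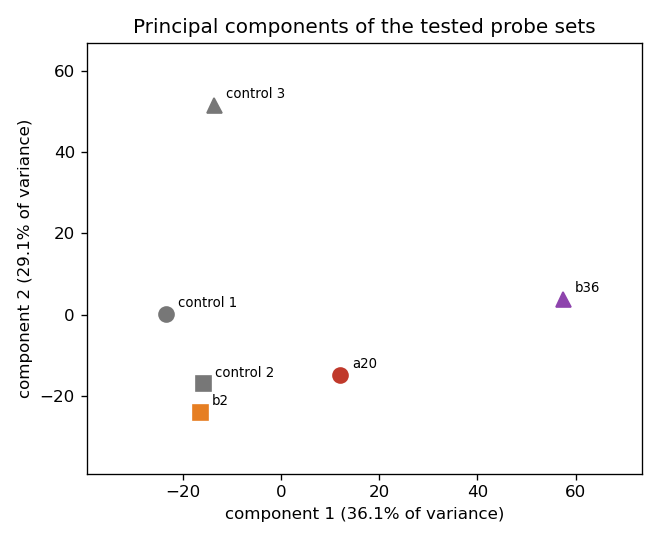
Positions of the 6 arrays on the first 2 principal components of the tested probe sets, with the share of variance on each axis; grey symbols are controls and coloured symbols are lines. Line b36 lies apart on component 1 at 57.4 and control 3 on component 2 at 51.8, and the groups do not form separate clusters.

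The array also holds 64 probe sets for reporter and selection marker genes, which were left out of the test. On all 6 arrays, 61 of them stayed within 0.1 of the floor. RPTR-Ta-X17220-1_at read 4.85 in line b36 and 2.18 on the other 5 arrays, so that the group means differed by 0.89. In a separate limma fit that included the reporter probe sets its adjusted p was 0.848, for a signal on 1 array against values at the floor.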

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

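The tests in this part were chosen only after the signal was seen. RPTR-Ta-X17220-1_at, a reporter probe set outside the main test, read 4.85 in line b36, 2.66 above the highest control at 2.18, and was picked out because it is a signal in data the comparisons do not use. A raised background on this array stays open. In b36, 0 of the other 63 reporter probe sets lay over 0.5 above the highest control. Only 2 of these left the floor by more than 0.1 on any array, and values held at the floor can hide a small rise. RPTR-Ta-X17220-1_at itself read 2.18 on the other 5 arrays, so a rise as large as its own was not seen in the other reporter probe sets. A sequence of the transformation vector stays open too: the signal was in 1 line of 3, and the labels used here do not give the vector of each line, so a vector carried by b36 alone may produce it and cannot be told apart from cross-hybridisation in 1 sample. No biological explanation was tested.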

How the results depend on the processing

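Removing control 3 and b36 together was chosen after seeing the data, and the counts at an unadjusted p and of separated probe sets were added as measures then too, as were the estimated correlation and fry with no filter or with an array left out; the other settings were planned. No paired analysis was possible because the labels carry no replicate numbers shared between the groups. Limma's count of 0 became 1 with median centring and 1 with quantile normalization, the unnamed probe set with the smallest p in both, and stayed 0 under all other settings run and with any 1 array left out (0 to 0). The count at an unadjusted p under 0.05 (1483) was 889 in the upper 25% of mean values, 950 by the pooled-variance test, 31 with 1 value for each of 571 genes, 924 without control 3 and b36, and 1024 to 2457 with 1 array left out, highest without b2. The separated 2-fold count (102) was 61 in the upper 25%, 5 with 1 value per gene, 49 without control 3 and b36, and 61 to 193 with 1 array left out: 61 without control 3, 65 without b36, 187 without control 2 and 193 without b2. The upper-25% and per-gene counts come from fewer probe sets; for the others, which moved either way with which array was left out, the cause was not tested. Called gene lists (0) were 1 with no filter, the fructan exohydrolases, and 0 to 1 with 1 array left out: carbon fixation without control 3 and the exohydrolases without a20. These calls rest on camera's preset correlation: with an estimated one the adjusted p was 0.607 with no filter, 0.296 without control 3 and 0.592 without a20, and 0 lists were called with all arrays by it or by fry. With 1 array left out, fry's test for change in either direction called 0 to 1 list; it gave the histone list an adjusted p of 0.00118 without a20 and 0.0270 without b2, and the anther and pollen list 0.00185 without b36, against 0.618 for each with all arrays; both lists hold a probe set with repeated low values, and the cause was not tested. The list test with 1 value per gene was not run, as 0 lists had 3 genes. Line counts with 1 control left out were 382 to 565 for a20, 236 to 505 for b2 (505 without control 1, 502 without control 2) and 992 to 1078 for b36. The lowest correlation between arrays was 0.986 and 0.994 with no filter, which adds floor values. For 40 named probe sets under the alternatives, 2 values (both for the same unnamed probe set) passed the threshold and 18 changed sign, none beyond 0.18; the setting with no filter and that with a variance trend leave each difference as it is and could not change a sign. The brighter PsbP probe set turned to -0.0045 with quantile normalization and the dimmest H2A-9 probe set to 0.00079 with median centring. With 1 array left out, signs changed within -0.029 to 0.037 for this PsbP probe set, -0.13 to 0.051 for the other, -0.061 to 0.24 for 1-FEH, -0.16 to 0.097 for RPS29, -0.018 to 0.062 for profilin, -0.029 to 0.068 for PsbO, -0.037 to 0.13 for COMT1, -0.18 to 0.23 for RPL9 and -0.043 to 0.12 for PER1. Probe sets at the floor of 2.18 limit what low signals can show.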

Other observations

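The tests in this part were chosen only after the patterns were seen; for the splits of the arrays, what to count at an unadjusted p and as separated was chosen after seeing the data, but before the other splits were computed. Control probe sets for wheat sucrose synthase, the enzyme that cleaves sucrose into fructose and a nucleotide sugar, were lower in the lines without passing the test: the 5' set differed by -0.65 with an SE of 0.26 and separated groups, the middle set by -0.39 and the 3' set by -0.20, each with a limma adjusted p of 0.848. Control 3 was the highest array on all 3 sets, and without it they differed by -0.50, -0.20 and -0.08; the 5' set was at -0.42 without b2. The 3' minus 5' difference of this gene was 0.449 higher in the lines, and that of glucose-6-phosphate dehydrogenase 0.228 higher, so the graded values cannot be read as a lower transcript level alone. The control sets for ubiquitin, glucose-6-phosphate dehydrogenase and 18S rRNA differed by between -0.19 and 0.11. GA20ox1b (LOC543326), a gibberellin 20-oxidase, stood apart on 1 array: it read 6.04 in control 3, 1.03 above the mean of the other controls.

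LOC542773, LOC542774, LOC780687, LOC778386 and 6-FEH were higher in the lines by a median log2 difference of 2.43, and each was lowest in control 3. The amount of labelled cRNA hybridised is argued against, since the hybridisation spikes differed between groups by 0.167 with an SD of 0.302 over the arrays. Control 3 alone stays open: the median was 1.56 without it and 3.02 without control 2, but the probe sets were picked for lines above all controls, which fixes its sign. RNA degradation stays open too, as the 3' minus 5' difference of sucrose synthase was 0.449 higher in the lines and the order within the groups was mixed: b2, highest at 6.87, was the lowest line for each of these loci except LOC542774, but among controls all except LOC778386 followed the order of glucose-6-phosphate dehydrogenase (4.47, 4.41 and 4.34 in controls 2, 1 and 3), though not that of sucrose synthase. An effect of TaMYB13 overexpression on these loci remains a hypothesis: none passed the test, and they were picked because their groups were separated, so the sizes may be overstated. Such an effect also cannot be told apart from an effect of transformation, as the labels do not say whether the controls were transformed.

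Line b36 stood apart, with 491 probe sets at least 2-fold from both other lines against 106 for a20 and 314 for b2. It was the highest line in 34 of the 50 higher probe sets, against 11 for a20 and 5 for b2. It was the lowest in 21 of the 52 lower ones, against 15 for a20 and 16 for b2. RNA degradation is argued against for b36 as distinct from the other lines, since the 3' minus 5' difference of sucrose synthase in b36 was -0.464 relative to the highest other array, and that of glucose-6-phosphate dehydrogenase -0.361; that array, b2, lay at -16.5 on the first component, where b36 lay at 57.4. The amount of labelled cRNA hybridised stays open: the spikes in b36 exceeded the highest other array by 0.248, no more than the SD of 0.248 among the other 5. A difference between lines could also produce it and cannot be told apart from a difference between samples with 1 array.

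The 6 arrays can be split 3 against 3 in 10 ways, too few for a share under 0.05. The real split gave 0 calls and the highest other split 1, so that 10 of 10 splits gave as many. A real count of 0 fixes this outcome in advance, so it cannot decide anything. At an unadjusted limma p under 0.05 the real split gave 1483 against at most 1944, and 5 splits gave as many. For probe sets that were also separated and at least 2-fold apart, the real split gave 102 against at most 99. That 99 came from controls 1 and 2 with b2 against the other arrays. For this count 1 split, the real one, gave as many.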
